A study of Mus musculus with 12 samples.

How the data were processed

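Total RNA of Prmt5 F/F ER mouse cells (mixed C57BL/6 and 129 background) was sequenced, per the labels, from 12 libraries: 3 with ethanol and 3 with 4-OHT for each of NPC and MEF. NPC were E14.5 cortical neurospheres at day 4 with EGF and FGF, and MEF were passage 1 E14.5 fibroblasts grown to confluence, per the labels. Libraries were made with TruSeq v2 and read on an Illumina HiSeq, per the labels. Base calls came from CASAVA 1.8 and reads were aligned to mm9 with TopHat2 2.03 and Bowtie2 2.0.0.6, per the submitters' processing notes. Expression was compared with Cuffdiff 2.02 and splicing with MATS, whose version is not stated, per the submitters' processing notes.

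The 4 deposited tables hold 1 expression and 1 splicing comparison for each cell type. The expression tables give 1 RPKM value for each arm, per the file headers, so no replicate spread can be computed from them. The log2 fold change of 4-OHT over ethanol and the p-value of Cuffdiff were deposited by the authors beside it, and the log2 value was recomputed from the RPKM values as a check. The deposited p-value is not adjusted, and listed genes all have p under 0.05 and a change of over 1.5-fold, so a gene not listed was either untested, at a higher p or less changed. The splicing tables give, per the file headers, the count of reads for the inclusion and exclusion form of each event in 1 ethanol and 1 4-OHT library under a pair code. They give the inclusion level as a fraction of 1, and its difference, as deposited by the authors. Listed events have a deposited p-value under 0.05 and a difference over 0.2 in 2 or 3 of the 3 pairs, so the remaining pair of many events is unknown and mean differences over listed pairs are biased upward. Total counts per library are not given in the sources used here. Of the events, 10 in NPC and 3 in MEF had fewer than 20 reads in an arm.

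The design chosen before the data were examined assumed adjusted p-values. The tables hold unadjusted ones, so genes and events were taken as listed. As a stricter view, an upper bound of the Benjamini-Hochberg adjusted p was computed, counting all 55341 gene names of the annotation as tested. A gene under 0.05 by that bound passes whatever the number tested. Inclusion levels were averaged over the listed libraries of each arm, with the SD and the number of libraries. For events listed in 3 pairs, an exact permutation test of 3 against 3 libraries was run, whose smallest two-sided p is 0.1. For the Mdm4 exon, an exact test of its reads stratified by pair and an exact sign-flip test over pairs were added after its values were seen.

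Pair codes match no label. They were checked by correlating, over events listed in 3 pairs, each library's deviation from its arm mean. Libraries with the same code correlated at 0.177, 0.160 and 0.123 over 57 NPC events and at 0.232, 0.665 and 0.252 over 8 MEF events, each over 0.1 and above the highest value with another code. These events were listed for a difference over 0.2 in every pair, which by itself favours a positive correlation within a code. The check therefore cannot show that codes mark shared cultures, and no test was run on it. The pairing was kept as deposited, as a replicate block. The Prmt5 events were left out of this check.

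Direction within event classes was tested with two-sided exact binomial tests, and between retained introns and skipped exons with Fisher's exact test, with Benjamini-Hochberg adjustment over 6 tests. Gene lists of 13 kinds, fixed beforehand, were tested for direction against the other listed genes of the same table with Fisher's exact test, adjusted over the lists with at least 5 listed members. They cover p53 targets, cell cycle, DNA repair, spliceosome, neural progenitors, neurons, glia, extracellular matrix, immune cells, endothelial and blood cells, the integrated stress response, interferon and chromatin. Whether a list or an event class is listed more often than others was not tested, because the tested background is unknown. Events were called shared with the same coordinates, and the agreement expected from the direction of each class, a test added after the values were seen, took the class shares of events that are not shared. Correlations of log2 fold changes used 100000 permutations. A difference of the change between cell types was tested for the 49 genes listed in both, with standard errors derived from the deposited p-values under a normal distribution, adjusted over the 49 genes. Deposited p-values under 2.3e-16, among them values of 0, were set to that floor, so the standard errors of such genes are upper limits.

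Coordinates are 1-based in mm9. The GENCODE annotation used is of another build, GRCm38, so exons and introns were matched within the same Ensembl gene by their lengths and neighbors, never by position. This matched 129 of 135 skipped exons and 80 of 82 retained introns in NPC, and 32 of 32 and 21 of 21 in MEF. The planned scoring of splice sites was not run, since it needs a genome of the files' build. Junction sequences of 50 bases on each side were searched with blastn 2.17.0 against 13607 pseudogene transcripts, and a copy needed 90% identity over 80 bases. An event is called all-or-none where, in a listed pair, one form has 0 reads in one arm and at least 20 in the other. Symbols in the MEF splicing table had lost the letters na, so that Dnajc8 was restored from its identifier.

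Named genes were chosen by a rule fixed before the data were examined. It took Prmt5, Mdm4, Cdkn1a, Mdm2, Ccng1 and Trp53 where listed, the 10 largest rises and falls at 1 RPKM or more in the higher arm, up to 4 members of each list with at least 3 listed, and the 10 largest genes in both cell types. For splicing it took Mdm4, the 5 largest rises and falls of skipped exons and retained introns with at least 20 reads in each arm, the 2 largest of other classes, the 10 largest shared events and up to 4 of the lists. List members that ran against their list, and listed members of lists too small for the rule, were named as well, after their values were seen. Alternatives tried were stricter p-values (0.01 and 0.001), an absolute log2 fold change of at least 1, at least 1 or 5 RPKM, pseudocounts of 1 and 0.1, at least 20 or 50 reads, inclusion differences of 0.2 and 0.1, 1 event per gene, and leaving out each pair. Tests were tested on simulated data: the blocked read test called 94% of 200 changed NPC events and 3% of 200 unchanged ones, and of 1000 random NPC lists 1.9% had Fisher's exact p-values under 0.05. Changed events were simulated with a difference of 0.3 from starting levels in the middle of the range. The 94% therefore does not cover events whose level starts near either end. The simulated reads held counting error but no further spread between libraries. The random lists held genes drawn at random, not genes regulated together. These rates therefore do not cover either source of excess calls. Computing used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.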

Results

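RNA was sequenced from 12 libraries in 4 groups of 3. Neural progenitor cells (NPC), grown as neurospheres from the E14.5 mouse cortex, and primary embryonic fibroblasts (MEF) of the same stage carried the genotype Prmt5 F/F ER, in which 4-hydroxytamoxifen (4-OHT) removes Prmt5. PRMT5 is an arginine methyltransferase whose substrates include Sm proteins of the spliceosome and histones. Cells received 50 nM 4-OHT or ethanol for 24 h. The series title poses the question of how PRMT5 acts on constitutive and alternative splicing and on Mdm4, a negative regulator of p53. Library totals are not given in the sources used here, so the depth behind the expression values is unknown. Splicing events carried a median of 89 reads with ethanol and 96 with 4-OHT in NPC, and 72 and 78 in MEF. None of the 12 libraries is labelled as 4-OHT-treated cells without the conditional allele, so 4-OHT and Prmt5 loss change together in each comparison. The labels do not say that replicates were separate cultures or animals, so the source of any spread between libraries is not stated. Of the tests run here, only the exact permutation tests of inclusion levels and the sign-flip test took libraries or pairs as units. Tests of gene lists, event classes, directions and correlations ran over genes or events, and the stratified test over reads. The deposited splicing p-values compare libraries within a pair. These p-values therefore do not measure the spread between replicate libraries.

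Prmt5 itself fell in both cell types. The authors' deposited table gives 33.4 RPKM with ethanol and 4.92 with 4-OHT in NPC, a log2 fold change of -2.76. In MEF the authors' deposited table gives 21.0 and 3.76 RPKM, a log2 fold change of -2.48. Reads over a 164 bp Prmt5 coding exon, at 55132128 to 55132291 of chromosome 14 in mm9, were nearly lost. Its inclusion level in NPC was 0.882 ± 0.076 (SD, n = 3) with ethanol and 0.007 ± 0.008 (SD, n = 3) with 4-OHT, with 1279 and 2 inclusion reads. In MEF the level was 1 in the 3 ethanol libraries and 0 in the 3 libraries with 4-OHT, with 856 and 0 inclusion reads. By the lengths of the exon and its introns it matches exon 7 of 17 of a GENCODE transcript. The labels do not say which exon is flanked by loxP sites.

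In NPC, Prmt5 loss was accompanied by a broad change in expression, with 2416 genes listed as changed, 1367 higher and 1049 lower. Several of the largest rises at 1 RPKM or more in the higher arm were genes with low starting levels: Ptprv, a receptor-type phosphatase gene, went from 0.138 to 2.82 RPKM in the authors' deposited table, and the meiotic cohesin gene Rec8 from 0.392 to 6.01 RPKM. Cryab, a small heat shock protein gene, rose from 2.79 to 22.6 RPKM and the mitochondrial creatine kinase gene Ckmt1 from 1.68 to 13.5 RPKM in the authors' deposited table. Icam1, Car10 and Sec14l5 rose with log2 fold changes of 3.37, 3.09 and 3.06 in the authors' deposited table. After Prmt5, the largest falls under the same limit were in Pnpla3, Spata24 and the Notch effector Hes5, with log2 fold changes of -2.05, -1.85 and -1.73 in the authors' deposited table. Rnaseh2c, which encodes a subunit of RNase H2, went from 19.0 to 5.77 RPKM and D2Ertd750e from 42.3 to 14.6 RPKM in the authors' deposited table. The median fold change was 1.99 among higher genes and 1.71 among lower genes. The majority turned with the level of expression: of the 1168 genes with at least 5 RPKM in the higher arm, 461 were higher and 707 lower. The deposited p-values are not adjusted and the libraries of an arm share 1 value, so no spread between replicates can be given for these genes.

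All 30 listed p53 targets and regulators were higher in NPC, of 43 fixed beforehand. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 65.1 to 216 RPKM in the authors' deposited table. Ccng1 and Mdm2, an E3 ligase gene that p53 induces, rose with log2 fold changes of 1.28 and 1.08 in the authors' deposited table. The death receptor gene Fas and the desmosome gene Perp had log2 fold changes of 2.92 and 3.53 in the authors' deposited table. The apoptosis genes Bbc3 and Pmaip1, chosen after their values were seen, had log2 fold changes of 1.51 and 1.63 in the authors' deposited table. No member was lower, against 44.0% of the other listed genes (Fisher's exact test, p = 4.18e-08, Benjamini-Hochberg adjusted p = 1.39e-07 over 10 lists). An adjusted p under 0.05 was certain for 29 members adjusted over the list alone and for 28 over all genes. Mdm4 and Trp53 are not among the genes listed as changed, and whether they were tested is not known.

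Listed genes of proliferation went the other way in NPC. Of 81 cell cycle genes 72 were listed, and 70 of these were lower, among them Mcm7 of the replicative helicase, from 87.1 to 37.3 RPKM in the authors' deposited table. Thymidine kinase Tk1, topoisomerase Top2a and the proliferation marker Mki67 fell with log2 fold changes of -1.21, -1.08 and -1.07 in the authors' deposited table. The exceptions were the D-type cyclins Ccnd1 and Ccnd2, with log2 fold changes of 0.69 and 0.98 in the authors' deposited table. The lower share of 97.2% compared with 41.8% of the other listed genes (Fisher's exact test, p = 1.00e-23, adjusted p = 1.00e-22). Adjusted p-values under 0.05 were certain for 72 members adjusted over the list alone and 70 over all genes.

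Of 86 DNA damage response and repair genes 44 were listed, and 40 of these were lower. Recql fell from 13.8 to 5.46 RPKM in the authors' deposited table, and Brca1 and Chek1, chosen after their values were seen, had log2 fold changes of -0.84 and -0.74 in the authors' deposited table. The members that rose were Ercc5, Mgmt, Parp3 and Rev1, with log2 fold changes of 1.26, 1.16, 1.14 and 0.82 in the authors' deposited table. The test gave p = 4.31e-11 (Fisher's exact test, adjusted p = 2.16e-10). With a log2 fold change of at least 1 required, 4 of 7 members were lower and the adjusted p was 0.0908 (Fisher's exact test). Over the list alone 44 members had an adjusted p under 0.05, and 41 over all genes.

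Of 128 genes of Sm proteins, PRMT5 partners and the spliceosome, 14 were listed in NPC, and 12 of these were lower. Besides Prmt5 these included Gemin6 of the SMN complex, from 16.5 to 7.51 RPKM in the authors' deposited table, and Snrnp35 and Dhx38, with log2 fold changes of -0.83 and -0.73 in the authors' deposited table. Prpf3 and Snrnp200 were the higher members, with log2 fold changes of 0.63 and 0.67 in the authors' deposited table. The lower share was 85.7% against 43.2% elsewhere (Fisher's exact test, p = 0.00177, adjusted p = 0.00441), with 14 members under an adjusted p of 0.05 adjusted over the list alone and 13 over all genes. Without Prmt5 the adjusted p was 0.00862 (Fisher's exact test, 11 of 13 lower). Set against other genes with at least 5 RPKM, of which 60.2% were lower, the call ended (Fisher's exact test, adjusted p = 0.0741, and 0.101 without Prmt5). The 6 listed chromatin regulators were all lower, including Ezh2, from 60.0 to 36.6 RPKM, and Hmga1, from 42.7 to 26.0 RPKM, in the authors' deposited table. Their test gave p = 0.00665 (Fisher's exact test, adjusted p = 0.0111), with 5 members adjusted over the list alone and 5 over all genes. At 1 RPKM or more in the higher arm, 5 members were left and the adjusted p was 0.0800 (Fisher's exact test), and at 5 RPKM or more it was 0.163 (Fisher's exact test).

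Listed genes of glia and neurons were mostly higher in NPC, over a wide range of levels. Of 14 listed astrocyte and oligodendrocyte genes 13 were higher, with Gfap, an astrocyte filament gene, going from 0.221 to 1.10 RPKM and the myelin gene Mag from 0.180 to 0.919 RPKM in the authors' deposited table. The astrocyte gene Aldh1l1, chosen after its values were seen, rose from 67.7 to 118 RPKM in the authors' deposited table, and the member that fell was Ugt8a, with -0.61. Of 20 listed neuron and synapse genes 16 were higher, such as the glutamate receptor gene Gria1, from 0.188 to 1.73 RPKM, and, chosen after its values were seen, Syt11, from 81.0 to 135 RPKM, in the authors' deposited table. Neural progenitor and radial glia genes were split, with 5 higher and 3 lower. Hes5 was the lowest of these, while the inhibitor of differentiation gene Id1 and the endothelin receptor gene Ednrb had log2 fold changes of 1.04 and 0.90 in the authors' deposited table. Fisher's exact test of direction gave p = 0.00540 for the glial list (adjusted p = 0.0108), p = 0.0405 for the neuron list (adjusted p = 0.0450) and p = 1 for the progenitor list. Counts under an adjusted p of 0.05 were 13, 18 and 8 adjusted over the list alone and 13, 13 and 8 over all genes. The neuron result ended at 1 RPKM or more in the higher arm, with 7 of 10 members higher (Fisher's exact test, adjusted p = 0.229), at 5 RPKM or more (Fisher's exact test, adjusted p = 0.0573) and with a deposited p under 0.01 required (Fisher's exact test, adjusted p = 0.0986). Its direction against the other genes turned where a log2 fold change of at least 1 was required, with 22.2% of 9 members lower (Fisher's exact test, p = 1). The glial result ended where a log2 fold change of at least 1 was required (10 of 10 members higher, Fisher's exact test, adjusted p = 0.231).

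Most listed genes of the stress response and of the matrix were higher too. Of 33 genes of the integrated stress response and unfolded protein response 17 were listed, and 15 of these were higher, led by Nupr1, from 2.10 to 10.7 RPKM, and Trib3, from 0.667 to 3.33 RPKM, in the authors' deposited table. The amino acid transporter gene Slc7a3 and the glutathione-degrading enzyme gene Chac1 had log2 fold changes of 2.09 and 1.56 in the authors' deposited table. The unfolded protein response factor Xbp1 and the chaperone gene Hspa1b fell, with log2 fold changes of -0.69 and -0.81 in the authors' deposited table. Of 53 fibroblast and extracellular matrix genes 13 were listed, and all but Fbln1 were higher, among them Mmp2, from 0.666 to 2.38 RPKM, and Thbs2, from 0.195 to 1.01 RPKM, in the authors' deposited table. Fisher's exact test gave p = 0.0116 (adjusted p = 0.0145) for the stress list and p = 0.00944 (adjusted p = 0.0135) for the matrix list. Counts under an adjusted p of 0.05 were 17 and 13 adjusted over the list alone and 15 and 10 over all genes. Both calls ended where a log2 fold change of at least 1 was required (Fisher's exact test, adjusted p = 0.304 and 0.411). Markers of other cell types moved with these groups at low levels: the vessel genes Flt1 and Tek went from 0.0658 and 0.0804 to 0.118 and 0.140 RPKM in the authors' deposited table. The immune markers H2-Ab1 and Cd14 went from 0.325 and 0.569 to 0.908 and 1.12 RPKM in the authors' deposited table, and 4 interferon-stimulated genes were higher, with Gbp2 at 0.324 and 0.917 RPKM. These lists had too few listed members to test.

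**Figure D1:**
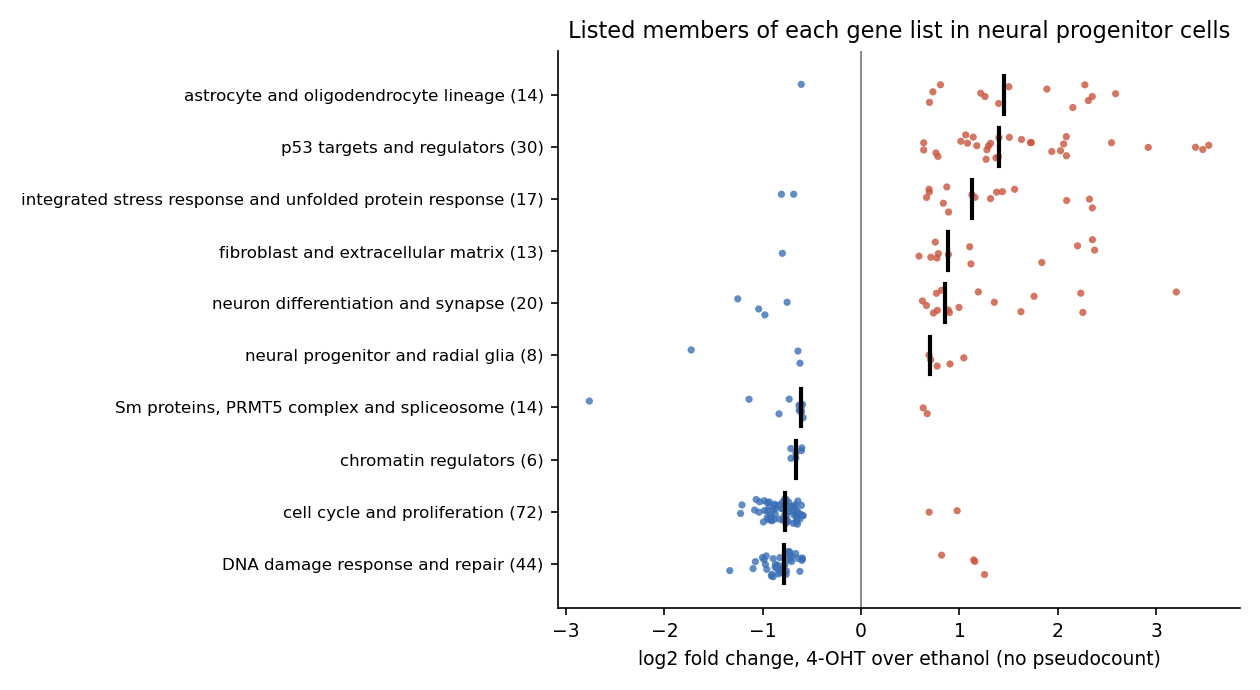
Each point is a gene listed as changed in NPC, placed by its log2 fold change (4-OHT over ethanol, no pseudocount), in the 10 gene lists with at least 5 listed members, whose number stands in brackets, and black bars are list medians. The p53 list lies wholly above 0, with a median of 1.40, and the cell cycle list almost wholly below, with a median of -0.77.

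Far fewer genes were listed in MEF, 111 in all, with 56 higher and 55 lower. After Prmt5 the largest falls at 1 RPKM or more in the higher arm were in U90926, Traf1 and Rasl12, with log2 fold changes of -1.68, -1.45 and -1.36 in the authors' deposited table. The metallothionein gene Mt2 followed, from 503 to 201 RPKM in the authors' deposited table. The chemokine gene Cxcl3, Chi3l1 and the haptoglobin gene Hp were also lower, with log2 fold changes of -1.32, -1.30 and -1.15 in the authors' deposited table. The largest rises at 1 RPKM or more were in the natriuretic peptide receptor gene Npr3 (1.37), Svop (1.31) and Arhgap20 (1.26), as log2 fold changes in the authors' deposited table. The smooth muscle myosin gene Myh11 went from 8.25 to 17.2 RPKM and the G protein regulator gene Rgs4 from 8.90 to 20.1 RPKM in the authors' deposited table. Most of these calls were weak: 96 of 111 genes had a deposited p between 0.01 and 0.05, and Prmt5 alone was sure to pass an adjusted p of 0.05 over all genes. The 11 cell cycle genes listed in both cell types all had higher p-values in MEF, where the smallest Cuffdiff p after Prmt5 was 0.000725. Ccnb2, with log2 fold changes of -0.88 in NPC and -0.85 in MEF, had Cuffdiff p-values of 1.53e-09 and 0.0224. Most of the 11 fell less in MEF, such as Top2a (-1.08 in NPC and -0.74 in MEF), while Birc5 fell more (-0.78 and -0.88). Listing in MEF also favours genes with larger changes there. The shorter list therefore does not by itself show smaller changes in MEF, and these genes do not show equal ones.

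Of the 81 cell cycle genes 11 were listed in MEF, and all 11 were lower, among them Tk1, from 18.9 to 8.80 RPKM, and Birc5, from 39.5 to 21.4 RPKM, in the authors' deposited table. Mybl2 and cyclin B2, Ccnb2, had log2 fold changes of -0.98 and -0.85 in the authors' deposited table. The lower share among the other listed genes was 44.0% (Fisher's exact test, p = 0.000253, the single list with enough members to test). None of the 11 was sure to pass an adjusted p of 0.05, either adjusted over the list alone or over all genes. Cdkn1a, Mdm2, Ccng1, Mdm4 and Trp53 are not among the genes listed in MEF, which does not show that they were unchanged. The p53 list holds Ano3 alone in MEF, with a log2 fold change of 1.01 in the authors' deposited table. The higher members of other lists were Jag1 and Ptprz1 for progenitors, Eln for matrix, Rgs5 for vessels, and Rsad2 and Oasl2 for interferon. The DNA repair, neuron, glial, immune, stress and chromatin lists had 0 listed members, and the spliceosome list held Prmt5 alone.

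Genes listed in both cell types mostly changed the same way. Of 49 such genes, 27 were lower in both and 15 higher in both. Cdkn3, a cyclin-dependent kinase phosphatase gene, had log2 fold changes of -1.42 in NPC and -1.02 in MEF in the authors' deposited table. For Svop, which encodes a synaptic vesicle protein, the authors' deposited table gives 2.63 and 1.31, and for Ppp2r2c 2.38 and 1.29. Dsp is listed with 2.38 and 1.03 in the authors' deposited table, but at 0.00506 and 0.0263 RPKM in NPC. The same-direction share was 85.7% (exact binomial test, p = 3.62e-07) and 41 of 48 without Prmt5 (p = 6.24e-07, exact binomial test). Across these genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.706 and a Spearman rho of 0.685. Both of these 2 relations had a permutation p of 1e-05, the smallest that 100000 permutations can give, and the same value after Benjamini-Hochberg adjustment. Without Prmt5 the Pearson r was 0.676, and without the 2 genes farthest from the NPC median it was 0.694. The listing leaves no small changes, with absolute log2 fold changes of at least 0.585 in NPC and 0.650 in MEF. The correlations therefore largely restate the shared direction. Whether the sizes of the changes agree was not tested apart from direction.

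**Figure D2:**
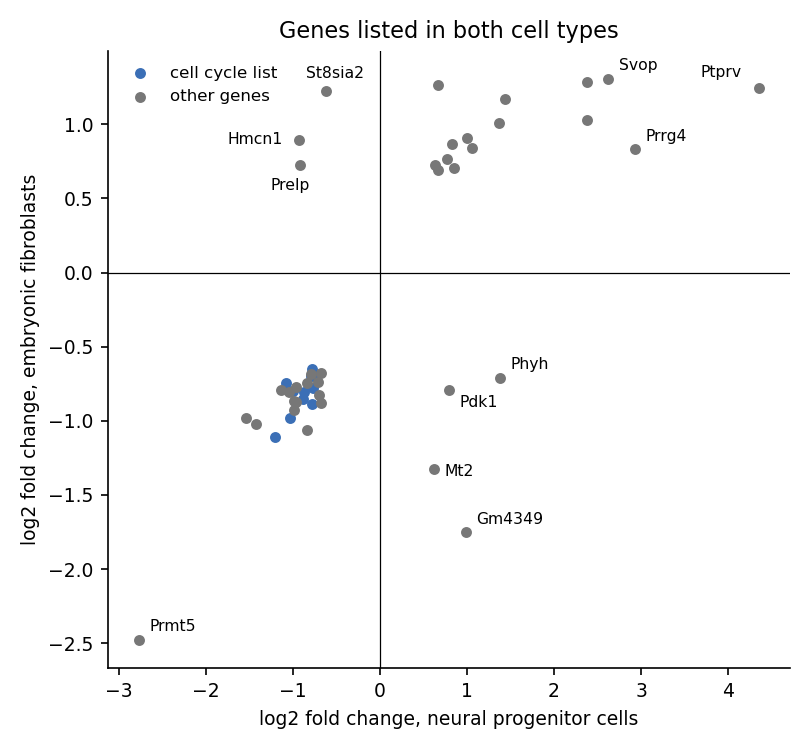
Each of the 49 points is a gene listed as changed in both cell types, placed by its log2 fold change (4-OHT over ethanol) in NPC on the horizontal axis and in MEF on the vertical axis, with the 11 genes of the cell cycle list in blue. The 27 genes lower in both lie in the lower left quadrant, with Prmt5 at its corner, and 7 genes lie in the quadrants of opposite direction.

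Splicing changed in NPC mainly through more retained introns and fewer included exons. The splicing tables list 255 events in 222 genes, of which 59 were listed in all 3 pairs of libraries. Of 82 retained introns, 79 had a higher inclusion level with 4-OHT, with a median difference of 0.341. Of 135 skipped exons, 84 were included less, with a median difference of -0.322, and 51 more. Alternative 5′ sites (14 of 20) and alternative 3′ sites (10 of 12) were more often higher. The 6 events of mutually exclusive exons, 4 of them higher, lay in 4 genes, with overlapping events of Tmem234 among the higher ones. The share of retained introns with a higher level was 96.3% (exact Clopper-Pearson 95% interval 89.7 to 99.2, exact binomial test, p = 3.80e-20, adjusted p = 1.24e-19 over 6 tests). The share of skipped exons with a lower level was 62.2% (interval 53.5 to 70.4, exact binomial test, p = 0.00568, adjusted p = 0.00568). Direction differed between these classes (odds ratio 43.4, Fisher's exact test, p = 4.12e-20, adjusted p = 1.24e-19). Events are not replicates and intervals cover counting error only. In 34 of the 255 events one form had 0 reads in one arm of a pair against at least 20 in the other arm, and without them the shares were 98.6% and 62.3%.

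In NPC, introns of DNA repair and chromatin genes were among those retained more. Fancg, of the Fanconi anemia core complex, had such an intron at 43019987 to 43020139 of chromosome 4. Its level went from 0.094 ± 0.031 (SD, n = 3) with ethanol to 0.810 ± 0.168 (SD, n = 3) with 4-OHT. Its reads were few, with 40 of 60 spliced with ethanol and 5 of 78 with 4-OHT. An intron of the mismatch repair gene Pms2, at 144689136 to 144689810 of chromosome 5, went from 0.093 ± 0.019 to 0.405 ± 0.056 (SD, n = 3). In the nuclease gene Mus81 the level went from 0.169 ± 0.021 to 0.471 ± 0.021 (SD, n = 2), with a splice junction that has a copy in the pseudogene Gm48985. The histone methyltransferase gene Setdb1 kept a 1080 bp intron at 95141188 to 95142267 of chromosome 3, at 0.203 ± 0.026 with ethanol and 0.514 ± 0.014 with 4-OHT (SD, n = 3), over 1602 and 3855 reads. In Hdac10 the level went from 0.120 ± 0.088 to 0.686 ± 0.077 (SD, n = 2), over 33 and 94 reads, of which 16 and 6 were spliced. Prmt5 had a retained intron too, at 0.040 ± 0.009 with ethanol and 0.431 ± 0.043 with 4-OHT (SD, n = 3). This intron is counted among those retained more. Since 4-OHT removes Prmt5 itself, its change cannot be told apart from the loss of sequence in that gene. Among the largest rises, those of Wdr75, Parl and Pafah1b1 to a level of 1, rest on arms with 0 spliced reads, and each of these junctions has a pseudogene copy. The introns of Lrif1, listed as 4933421E11Rik, and Glb1l also rose to a level of 1 with 0 spliced reads, and no copy was found for them. Against the trend, the Ccdc106 intron fell from 0.663 ± 0.293 to 0.164 ± 0.046 (SD, n = 3). Events listed in 3 pairs reach a permutation p of 0.1, the smallest that 3 against 3 libraries allow, which is not under 0.05. Their listing for a difference over 0.2 in each pair favours that value. Events listed in 2 pairs have no value for the remaining pair.

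The exon of Mdm4 was included less in NPC. This 68 bp coding exon, at 134901231 to 134901298 of chromosome 1 in mm9, matches exon 6 of 11 and its skipping shifts the reading frame. Its inclusion level was 0.710 ± 0.034 (SD, n = 3) with ethanol and 0.473 ± 0.041 (SD, n = 3) with 4-OHT, a difference of -0.237. Inclusion reads numbered 345 and 265, and skipping reads 54 and 115. The ranges of the arms did not overlap (exact permutation test, unpaired and two-sided, p = 0.1, the smallest possible). Within pairs the difference had an SD of 0.008 (n = 3, exact sign-flip test, p = 0.25, the smallest possible). The listed pairs of an event all have the same direction, which fixes the sign-flip value for an event listed in 3 pairs. A listed difference over 0.2 in each pair also favours arms that do not overlap. Neither of these 2 tests therefore adds much to the listing. The exact stratified test of its reads with the pair as block gave p = 2.94e-08, which takes reads as independent and follows a listing for p under 0.05 in each pair. A copy of the inclusion junction, by at least 90% identity over 80 bases, lies in the pseudogene Mdm4-ps, and whether its reads entered the counts was not tested. This exon is not listed in MEF, and a difference between the cell types was not tested. Mdm2 also lost an exon, chosen after its values were seen: the 131 bp exon at 117146710 to 117146840 of chromosome 10, a 5′ UTR exon, went from 0.880 ± 0.056 to 0.464 ± 0.013 in NPC and from 0.751 ± 0.049 to 0.535 ± 0.040 in MEF (SD, n = 2).

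The list of Sm proteins, PRMT5 partners and the spliceosome held 16 NPC events in 12 genes, 12 higher and 4 lower, with 2 of the events in Prmt5 itself. Luc7l, a U1 snRNP-associated factor, included a 71 bp exon more, from 0.270 ± 0.047 to 0.821 ± 0.003 (SD, n = 2), with a copy of the skipping junction in the pseudogene Gm7948. The events of Snrpc, down from a level of 1, and Rbm10, up to 1, rest on arms with 0 reads of one form and have pseudogene copies as well. Tia1, an RNA-binding splicing regulator, moved from 0.805 ± 0.008 to 0.526 ± 0.005 in a mutually exclusive exon (SD, n = 2). Among chromatin genes, Bptf gained inclusion of a 186 bp exon, from 0.295 ± 0.016 to 0.715 ± 0.010 (SD, n = 2). A 58 bp exon of Strada went from 0.306 ± 0.093 to 1 (SD, n = 2), and a 116 bp exon of the histone methyltransferase gene Setd8 from 0.283 ± 0.069 to 1 (SD, n = 3), over 49 and 33 reads. Among skipped exons with at least 20 reads in each arm, the largest losses of inclusion beside Prmt5 were in Kif3a and Tmbim6, again with 0 reads of one form in an arm, then in Ranbp17 and Crocc, from 1 to 0.194 ± 0.138 and 0.224 ± 0.136 (SD, n = 2). By list, NPC events numbered 3 in DNA repair genes, 5 in chromatin genes, 3 in p53 genes and 1 in neuron genes, and 0 in the others. Of the 79 events named by the fixed rule in both cell types, 37 had 0 reads of one form in one arm of a pair against at least 20 in the other, and further ones had 0 against fewer.

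**Figure D3:**
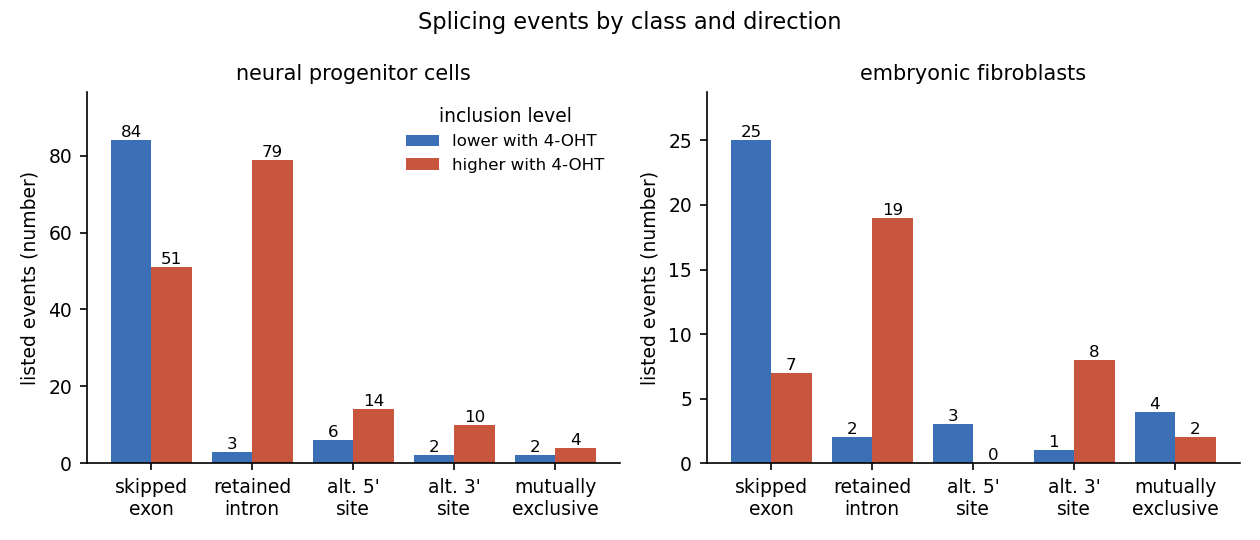
Bars count the splicing events listed in each class, with NPC on the left and MEF on the right, lower inclusion with 4-OHT in blue and higher inclusion in red. Retained introns are almost all higher (79 of 82 and 19 of 21), and skipped exons are more often lower (84 of 135 and 25 of 32).

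In MEF the same classes led, in fewer events. There were 71 events in 61 genes, 9 of them listed in all 3 pairs. Of 21 retained introns 19 were higher, and of 32 skipped exons 25 were lower, while alternative 3′ sites were higher in 8 of 9, alternative 5′ sites lower in 3 of 3 and mutually exclusive exons lower in 4 of 6. An exon of Pacrgl went from 0.793 ± 0.293 to 0.251 ± 0.021 (SD, n = 2), and an alternative 3′ site of Iffo1 from 0.399 ± 0.125 to 0.964 ± 0.051 (SD, n = 2). The Ptbp1 exon at 79322862 to 79322939 of chromosome 10 went from 0.824 ± 0.250 to 0.155 ± 0.047 (SD, n = 2), with 0 reads of one form in an ethanol library and copies of both forms in the pseudogene Gm18815. An intron of Nono, an RNA-binding protein gene, went from 0.033 ± 0.004 to 1 (SD, n = 3), with 0 spliced reads in a 4-OHT arm and a copy in the pseudogene Gm5171. Retained introns were higher in 90.5% (interval 69.6 to 98.8, exact binomial test, p = 0.000221, adjusted p = 0.000332) and skipped exons lower in 78.1% (interval 60.0 to 90.7, exact binomial test, p = 0.00210, adjusted p = 0.00252). The classes differed in direction (odds ratio 33.9, Fisher's exact test, p = 8.19e-07, adjusted p = 1.64e-06). In 26 of the 71 events, 36.6%, one form had 0 reads in one arm of a pair against at least 20 in the other arm. For skipped exons the call ended with a deposited p under 0.01 required, at 73.7% of 19 (exact binomial test, p = 0.0636).

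**Figure D4:**
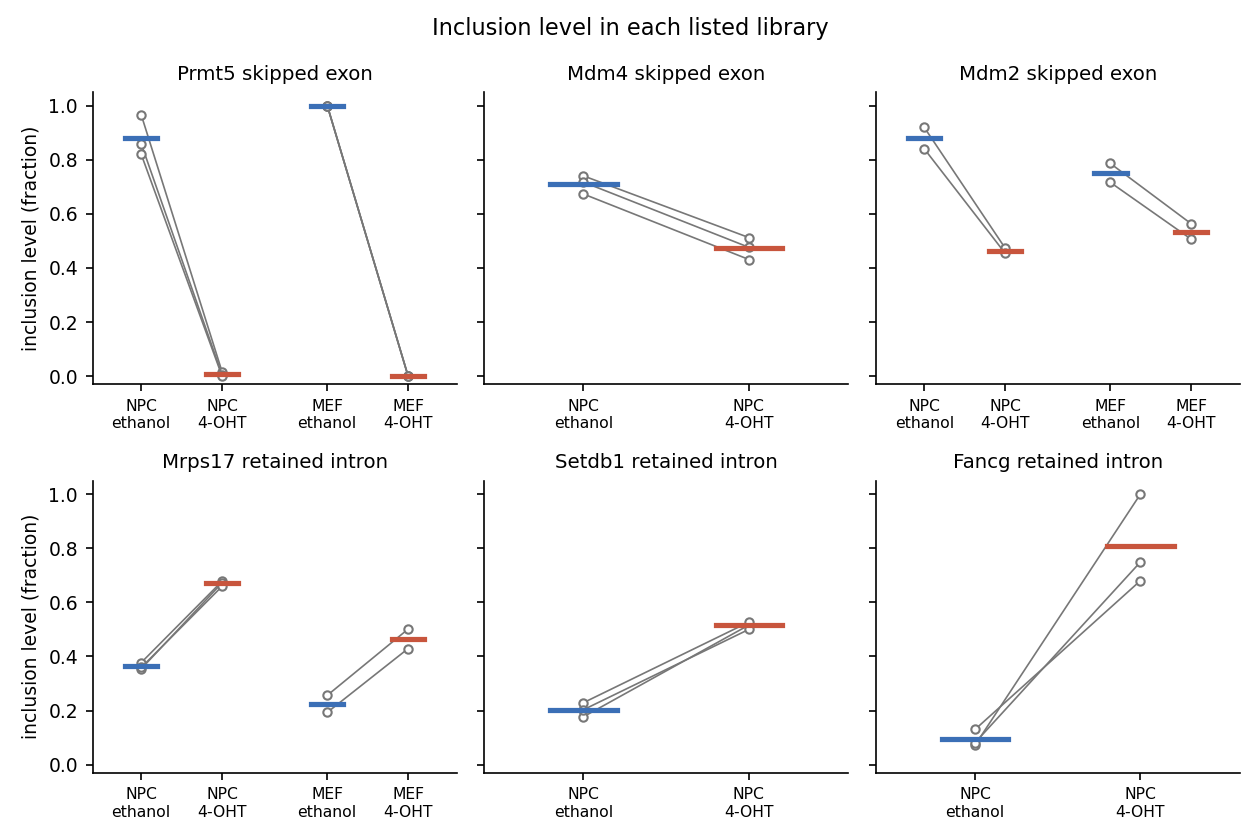
Open circles are inclusion levels (fraction of 1) in single libraries, joined within a pair, for the listed pairs of each event, and bars are means for ethanol (blue) and 4-OHT (red). The Prmt5, Mdm4 and Mdm2 exons lie lower with 4-OHT in each listed pair, and the introns of Setdb1, Fancg and Mrps17, the last chosen after its values were seen, lie higher.

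The cell types shared 20 events with the same coordinates, in 18 genes, and all 20 changed the same way. They were 10 retained introns, all higher, 7 skipped exons, 5 of them lower, 2 alternative 3′ sites and 1 mutually exclusive exon. The Timm10b intron, under the older name Fxc1, went from 0.117 ± 0.011 to 0.465 ± 0.033 in NPC (SD, n = 2) and from 0.157 ± 0.068 to 0.587 ± 0.361 in MEF (SD, n = 3), where a 4-OHT library had 0 spliced reads. Its spliced junction has a copy in the pseudogene Gm42786. Zfp740, a zinc finger gene, lost a 77 bp 5′ UTR exon, from 0.516 ± 0.054 to 0.229 ± 0.018 in NPC and from 0.851 ± 0.211 to 0.362 ± 0.057 in MEF (SD, n = 2). Tbc1d24 lost a 64 bp coding exon, from 1 to 0.583 ± 0.179 in NPC and to 0.657 ± 0.161 in MEF (SD, n = 2). The intron of the metalloprotease gene Adamts10 went from 0.486 ± 0.008 to 1 in NPC, with 0 spliced reads in a 4-OHT library, and from 0.437 ± 0.065 to 0.752 ± 0.025 in MEF (SD, n = 2). Among these, 2 events of Chtop, listed as 2500003M10Rik, share reads, and 7 of the 20 events had 0 reads of one form in one arm of a pair against at least 20 in the other. Against an even share the exact binomial test gave p = 1.91e-06, but classes such as retained introns mostly share a direction anyway. Without Prmt5 and with 1 of the Chtop events, 12.5 of 18 would run the same way from the class shares among events not shared (exact Poisson-binomial test, one-sided, p = 0.00105). The shared events made up 28.2% of those in MEF, and an overlap beyond chance was not tested because untested events are unknown.

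Genes with both a splicing event and a change in level were mostly lower in NPC. Of 31 such genes, 22 were lower, 71.0% against 43.1% of the other listed genes (odds ratio 3.23, Fisher's exact test, p = 0.00287). At 5 RPKM or more in the higher arm 17 of 23 were lower, but more of the other genes were too, and no difference was detected (73.9% against 60.3%, Fisher's exact test, p = 0.204). Mpdu1, a glycosylation gene, and Tmpo, a nuclear lamina gene, both chosen after their values were seen, fell from 61.6 to 38.1 RPKM and from 118 to 72.5 RPKM in the authors' deposited table. The Tmpo exon at 90616023 to 90616142 of chromosome 10 went from 0.853 ± 0.008 to 0.490 ± 0.022 (SD, n = 3) over 5150 and 1402 reads. In Ankle1, a nuclease gene, expression fell with a log2 fold change of -1.62 in the authors' deposited table. Its retained intron went from 0.442 ± 0.171 to 0.819 ± 0.257 (SD, n = 2). In MEF, Adamts10 and Prmt5 were the 2 such genes (Fisher's exact test, p = 1).

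Skipped exons in NPC had a median length of 100 bp, and 41.5% (interval 33.1 to 50.3) had a length divisible by 3. In MEF the median was 81.5 bp and the share 65.6% (interval 46.8 to 81.4). The share did not differ detectably between exons of lower and higher inclusion (Fisher's exact test, p = 1 in NPC and 0.374 in MEF). Of the exons matched by length to GENCODE transcripts, 82 of 129 in NPC and 22 of 32 in MEF were wholly coding. Introns with higher retention had a median of 218 bp in NPC and 272 bp in MEF. Set against the other introns of the same transcript, 45 of 77 in NPC and 12 of 19 in MEF were shorter than the median (exact binomial test, p = 0.171 and 0.359). Of matched retained introns, 77 of 80 in NPC and 18 of 21 in MEF lay between coding sequence.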

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

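The test of a difference between cell types was run over all 49 genes listed in both. It was not part of the design chosen before the data were examined. These 9 genes had a log2 fold change that differed between NPC and MEF at an adjusted p under 0.05, from standard errors derived from the deposited p-values. For the 7 of them with opposite directions the listing itself, at p under 0.05 in both tables, ensures an unadjusted p under 0.05 in this test, so it adds little to the opposite signs.

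Most of them ran in opposite directions. Phyh, a peroxisomal phytanic acid oxidation gene, was higher in NPC (1.38) and lower in MEF (-0.71) in the authors' deposited table, a difference of 2.09. The metallothionein gene Mt2 was 0.62 and -1.33 in the authors' deposited table, a difference of 1.95. Pdk1, a pyruvate dehydrogenase kinase gene, was 0.79 and -0.79 in the authors' deposited table, a difference of 1.59. Gm4349 was 0.98 and -1.75 in the authors' deposited table, a difference of 2.73, at under 1 RPKM in each arm, and 0.32 and -0.25 with a pseudocount of 1.

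Hmcn1, Prelp and St8sia2 ran the other way. Hmcn1, an extracellular matrix gene, was lower in NPC (-0.93) and higher in MEF (0.89) in the authors' deposited table, a difference of -1.83. Prelp, a matrix proteoglycan gene, was -0.92 and 0.72 in the authors' deposited table, a difference of -1.65. The sialyltransferase gene St8sia2 was -0.61 and 1.23 in the authors' deposited table, a difference of -1.84. All 3 lay under 1 RPKM in NPC, where their log2 fold changes were -0.34, -0.11 and -0.14 with a pseudocount of 1. Ptprv and Prrg4 rose in both cell types but further in NPC, by differences of 3.11 and 2.09 in log2 fold change from the authors' deposited table. With a pseudocount of 1 Ptprv was 1.75 and 0.64 and Prrg4 1.69 and 0.71, so much of that excess rests on low ethanol levels in NPC. Adjusted p-values ran from 8.42e-06 for Phyh to 0.0248 for Gm4349 (normal test of the difference, not an exact test). No explanation of these differences was tested.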

How the results depend on the processing

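Alternatives chosen only after the data were seen were the upper bound of the adjusted p, the omission of all-or-none events, the fit without a replicate block, 5 RPKM or no Prmt5 for gene lists and for genes with both changes, and fewer shared events. Of 138 alternative values for the comparisons, 102 were the same, 14 weaker, 1 reversed and 21 moved, the last all counts that fell because each alternative keeps fewer genes, events or pairs. Of the 102, the listing fixes 13, since every listed event passes an inclusion difference of 0.2, and nearly fixes the 4 on the replicate block, which leaves 85. Listed NPC genes numbered 861 at an absolute log2 fold change of at least 1, 1168 at 5 RPKM, and 194 and 534 with pseudocounts of 1 and 0.1, and MEF genes 45, 73, 10 and 31. MEF genes numbered 15 at p under 0.01 and 1 by the bound of the adjusted p. Events at p under 0.01 and 0.001 numbered 164 and 97 in NPC and 39 and 27 in MEF, and 45 in MEF without all-or-none events. Leaving out each pair gave 104 to 157 events in NPC and 20 to 36 in MEF. The replicate block left all 255 and 71 events under 0.05, as did the fit without it, but the listing of events nearly ensures this, so it does not show what the pairing changes.

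The share lower in the neuron list was 30.0% at 1 RPKM (Fisher's exact test, p = 0.206) and 23.5% at p under 0.01 (Fisher's exact test, p = 0.0887). With an absolute log2 fold change of at least 1 it was 22.2% and its direction against other genes reversed (Fisher's exact test, p = 1). That setting left shares lower of 57.1% for DNA repair and 0 for glia, matrix and the stress response, and 1 or 5 RPKM left 100% for chromatin, all no longer under an adjusted p of 0.05. At 5 RPKM the neuron share was 16.7% and that of the spliceosome 85.7%, or 84.6% without Prmt5, again no longer under it, beside a larger lower share of other genes. MEF skipped exons were lower in 73.7% at p under 0.01 (exact binomial test, p = 0.0636). Genes with a splicing event and a change in level were lower in 73.9% at 5 RPKM (Fisher's exact test, p = 0.204) and in 72.7% there without Prmt5 (Fisher's exact test, p = 0.277). Fewer members remained in each, except the spliceosome list, which kept all 14 of its listed members at 5 RPKM. Other causes were not tested. Of 397 alternative values for named items, 37 were weaker, all genes under 1.5-fold with a pseudocount, and 0 reversed. None could have reversed, because a pseudocount keeps the sign and the listed pairs of an event all have the same direction. The lack of reversals among named items therefore shows no robustness. Leaving out a library and a replicate block were not run for expression, which has 1 value for each arm, nor were splice sites, MEF lists with fewer than 5 members, or other splits of the samples. Read depth limits events with few reads, and library totals are unknown.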

Other observations

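The tests of chance in the fibroblast gene list were chosen only after results were seen, and the predictions of the other tests were written before they were run.

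Some of the 42 genes with the same direction in both cell types lie outside the lists, and those named here were chosen after their values were seen, with no test of a group. Hmgb2, a chromatin protein gene of dividing cells, fell from 130 to 65.9 RPKM in NPC and from 11.8 to 6.21 RPKM in MEF in the authors' deposited table. The histone variant gene H2afz fell from 459 to 235 RPKM and from 104 to 60.8 RPKM in the authors' deposited table, and Hmgn2 had log2 fold changes of -0.79 and -0.68. The microtubule regulator gene Stmn1 had log2 fold changes of -0.71 and -0.74 in the authors' deposited table. Mylk, the myosin light chain kinase gene, had log2 fold changes of 0.85 and 0.71 in the authors' deposited table. Limch1 had log2 fold changes of 0.67 and 0.69 in the authors' deposited table.

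The 3 genes of the DNA repair list with a retained intron in NPC, Fancg, Pms2 and Mus81, are not among those listed with a change in level. Outside that list, Mutyh, Rtel1 and Terf1, chosen after their values were seen, had a splicing event and a lower level. Mutyh, a base excision repair gene, fell from 3.90 to 2.40 RPKM in the authors' deposited table while its intron went from a level of 0.342 ± 0.077 to 0.835 ± 0.026 (SD, n = 2). The helicase gene Rtel1 fell from 13.9 to 8.89 RPKM in the authors' deposited table while its intron went from 0.103 ± 0.020 to 0.549 ± 0.042 (SD, n = 2). The telomere protein gene Terf1 fell from 10.1 to 6.60 RPKM in the authors' deposited table and lost inclusion of an exon, from 0.865 ± 0.025 to 0.567 ± 0.082 (SD, n = 2).

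All-or-none events were 13.3% of events in NPC and 36.6% in MEF. Loss of junction reads to pseudogene copies may account for some of them: 27 of 45 all-or-none skipped exons and retained introns had a copy, against 22 of 200 others (odds ratio 12.1, Fisher's exact test, p = 1.88e-11), which leaves 18 without one. A copy of either form counted, so 27 is an upper limit for copies of the missing form. In Tpm4 and Ppia in MEF the inclusion form was copied, but the skipping reads were 0 in an arm. Read depth was not matched between the groups of events. A fault that strikes either arm alike was not told apart from a real change, since 28 of 54 had their zero with 4-OHT (exact binomial test, p = 0.892). This count left out the Prmt5 exon, whose zeros lie with 4-OHT, and took events shared by the cell types once. Apart from the Prmt5 exon, the 4 events with a zero in both cell types, in Parl, Wdr75 and Chtop, had it in the same arm. The spliced junctions of all 3 genes have a pseudogene copy, however. An effect of Prmt5 loss remains open for these events.

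The weak p-values of the fibroblast list could mean chance listing. Against chance gene by gene, 41 of 48 genes also listed in NPC, apart from Prmt5, ran the same way (exact binomial test, p = 6.24e-07), and 30 of 37 outside the cell cycle list did (p = 0.000191, exact binomial test). Further proliferation genes such as Cdkn3 and Ube2c are among the 37 and genes regulated together are not independent, so a chance difference in growth between the MEF cultures stays open, as do the 62 genes not listed in NPC. A shared effect of Prmt5 loss and one of 4-OHT itself are not told apart.

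Exons with lower inclusion may carry a weaker donor on the exon side: 67.3% of 101 ended in G, against 87.1% of the exons upstream of them (exact McNemar test, p = 0.00166). No difference from exons with higher inclusion was detected, with 67.9% of 53 (Fisher's exact test, p = 1). The exons upstream of these ended in G in 71.7%, a pairing that was not tested. The part of this base in the response to Prmt5 loss is open.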
